A study of Drosophila melanogaster with 12 samples.

How the data were processed

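The deposited values were signal intensity values from MAS5 per the submitters' processing notes, without a stated version, and were kept as deposited by the authors. The 12 arrays held 4 groups of 3 biological replicates: cells of wild-type or slbo mutant ovaries, either isolated by a CD8 tag driven by slbo-Gal4 and called migratory here, or left over and called nonmigratory. Females were aged 2 to 7 days per the labels, 1 mutant nonmigratory array had no age label and another had no genotype label, so its genotype was read from its title. The number of arrays limits the precision of every estimate. Trimmed means lay between 150.026 and 150.030, and correlations between arrays of a group between 0.924 and 0.957.

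Of 14010 probe sets 44 were controls, 12442 had 1 gene, 327 had several genes and 1197 had no gene in the table used. They represented 10843 genes, 1209 of them with more than 1 probe set, where the probe set with the highest mean log2 signal was used, and 0 symbols were updated. Signals were transformed as log2 after adding 5% of the trimmed mean, 7.50. Of 12367 features, 8978 that exceeded the 40th percentile in at least 3 arrays were tested, comprising 7920 genes and 1058 unnamed probe sets. limma 3.58.1 in R 4.3.3 fitted 4 group means with an intensity trend in the variance and 8 residual degrees of freedom. The median SE was 0.302 for a comparison of 2 groups, 0.427 for the interaction and 0.213 for the average over genotypes. Calls used Benjamini-Hochberg adjusted p at 0.05 over the 8978 features of each comparison. Named genes were slbo, and in each direction the 8 largest log2 changes among called genes with a symbol other than a CG or CR number, values that did not overlap between the groups, and a mean log2 signal in the brighter group above the median. For mutant against wild-type nonmigratory cells and for the average 4 were taken in each direction. Where fewer than 5 passed, the 5 with the lowest unadjusted p were used. From each list that passed or is described, up to 4 called members with the lowest p were named, or 2 members given as values where none was called. Any other gene is stated as picked out after the values were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

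Of 31 gene lists 29 had at least 5 tested members and were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted by Benjamini-Hochberg within a comparison. The 3 further lists named below were adjusted over those 3 only, so their adjusted p cannot be compared with those of the 29. The lists came from general knowledge, the muscle list holds ldbr by mistake, and the slbo-dependent and polar cell lists were too short. Probe sets of lysozyme genes can bind transcripts of related genes, and several eggshell probe sets were near the top of the signal range. Samples, comparisons, lists and most alternatives were set before the data were examined; covariates for the GAPDH ratio and the gut list, the fit of only 2 groups for slbo, bounds on low signals and 3 further lists were chosen after seeing the data. Where a group's mean signal did not exceed the mean 95th percentile of 23 absent control probe sets, the fold was given as a bound, the brighter group against the higher of the signal and that percentile on each array, and no higher than the fitted fold. Exact permutation tests compared 6 with 6 arrays. The alternatives were quantile normalization, median centring, no filter or a filter at the 60th percentile, an added constant of 1% or 20%, no variance trend, array weights, fits of only 2 groups, means over probe sets, a replicate block and leaving out each array. The GAPDH ratio differed between fractions, and the gut list mean between genotypes and between the mutant fractions. Fewer calls with either as a covariate therefore do not show a cause.

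A test changed 200 features per comparison, divided equally between changes of 1 and 2 log2 units. With 1 log2 unit the recovered share was 35% and 38% between fractions of wild type and mutant, 38% and 42% between genotypes in migratory and nonmigratory cells, 23% for the interaction and 61% for the average. With 2 log2 units it was 77%, 71%, 80%, 83%, 64% and 100%. False calls made up 5.08%, 2.68%, 4.84%, 6.02%, 3.33% and 5.29%. Of the lists, 0 unchanged lists were called, and 1 list raised by 0.5 was called.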

Results

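The slbo transcript itself was the first readout of the mutant. Its mean signal was 213 (SD 55.7, n = 3) in wild-type migratory cells, 126 (SD 20.2) in wild-type nonmigratory cells, 43.6 (SD 8.17) in mutant migratory cells and 63.1 (SD 38.2) in mutant nonmigratory cells. In migratory cells slbo fell by 2.09 on the log2 scale in the mutant (4.27-fold, SE 0.404, n = 3 per group, Benjamini-Hochberg adjusted p = 0.0130 by limma). It was not called between mutant and wild-type nonmigratory cells (log2 -1.11, adjusted p = 0.351), nor between the fractions of the wild type (log2 0.71, SE 0.404, adjusted p = 0.342) or of the mutant (log2 -0.27, adjusted p = 0.758). Mutant nonmigratory replicate 2 had a signal of 19.0, against 87.3 and 82.9 on replicates 1 and 3. Both log2 values that use mutant nonmigratory cells therefore depended on single arrays. For the targeted gene slbo the change in migratory cells lay between -2.25 and -1.71 in all settings run. It no longer passed with the GAPDH 5' to 3' ratio (log2 -1.91, adjusted p = 0.154) or the gut list mean (log2 -2.04, adjusted p = 0.492) as a covariate, both chosen after the values were seen. The call was also lost without wild-type migratory replicate 1 (log2 -1.90, adjusted p = 0.0614), mutant migratory replicate 1 (log2 -2.11, adjusted p = 0.0511) or mutant migratory replicate 3 (log2 -1.97, adjusted p = 0.0606), and over all settings the adjusted p ranged from 0.000951 to 0.492. The slbo values came from 1 probe set, and its place relative to the mutant lesions was not given.

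**Figure D1:**
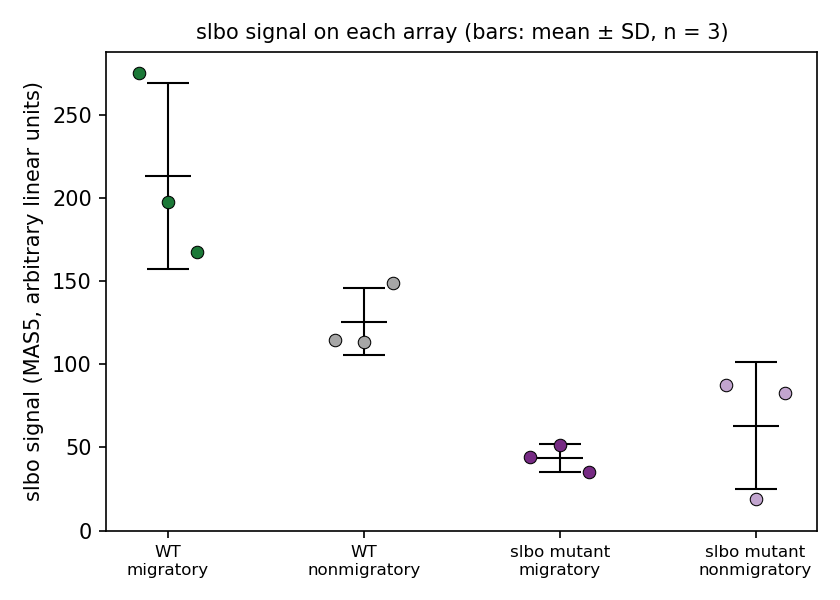
Signal of the slbo probe set on each of the 12 arrays, by genotype and cell fraction. Each point is 1 array and the bars are the means of 3 arrays.

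In wild-type ovaries the migratory fraction carried high levels of yellow-k, a member of the yellow gene family, which rose 10.5-fold over nonmigratory cells (log2 3.40, SE 0.173, n = 3 per group, adjusted p = 4.95e-08). The neprilysin-like gene goe (log2 2.91, SE 0.210), the chitin deacetylase gene Cda5 (log2 2.46, SE 0.499), the ABC transporter gene osy (log2 2.40, SE 0.262) and the glutathione transferase gene GstD4 (log2 2.26, SE 0.179) rose as well. The serine protease gene teq (log2 2.15, SE 0.154), the RNA-binding protein gene cpo (log2 2.12, SE 0.517) and whe (log2 2.07, SE 0.536) completed the largest increases. For teq, the other 3 probe sets gave -0.32, -0.71 and -0.36 and none passed, so that its rise rested on 1 probe set. For osy, the other 2 probe sets gave 1.90 and 0.20. The largest decreases included the serine hydroxymethyltransferase gene Shmt (log2 -2.40, SE 0.385), the collagen IV gene vkg (log2 -2.07, SE 0.173), the Notch target E(spl)malpha-BFM (log2 -1.96, SE 0.510) and the lipid phosphatase gene laza (log2 -1.95, SE 0.335). The iron regulatory protein gene Irp-1B (at least 5.21-fold), the cystathionine beta-synthase gene Cbs (at least 3.50-fold), GstE14 (at least 3.06-fold) and l(1)G0020 (at least 2.95-fold) fell to mean signals under the 95th percentile of absent control probe sets, so that only a bound can be given. In all, 825 of 8978 features were called at n = 3 per group, 383 higher and 442 lower in migratory cells, of which 138 and 163 changed at least 2-fold. With arrays centred on their medians the split for WT migratory vs nonmigratory was 366 higher and 273 lower. The count was 518 without wild-type migratory replicate 1, 537 without wild-type migratory replicate 3 and 451 without wild-type nonmigratory replicate 2.

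Adhesion, polarity and junction genes were the most raised of the morphogenetic groups in wild-type migratory cells. Of 42 members 13 were higher, 1 was lower and 28 were not called, and 14 were higher and 1 lower when adjusted over the list alone (median log2 0.42; camera adjusted p = 1.48e-05, and 0.113 with an estimated correlation). They included Fas1 (log2 1.28), the septate junction genes Gli (log2 1.28) and kune (log2 1.40), and the apical polarity gene crb (log2 0.91). Of 44 actin cytoskeleton genes 6 were higher and 38 were not called, with 7 higher when adjusted over the list alone (median log2 0.34; camera adjusted p = 0.000735, and 0.113 with an estimated correlation). Capping protein alpha, cpa (log2 1.17), the fascin gene sn (log2 0.87), Cortactin (log2 0.78) and the myosin light chain gene Mlc-c (log2 0.73) were among them. Of 32 border cell migration genes 3 were higher, 29 were not called and 3 were higher when adjusted over the list alone (median log2 0.28; camera adjusted p = 0.00373, and 0.113 with an estimated correlation). These were l(2)gl (log2 1.10), sn and the alpha-catenin gene alpha-Cat (log2 0.66). Of the genes expected to depend on slbo, a list too short to test, shg (log2 0.49, adjusted p = 0.207), jing (log2 0.31, adjusted p = 0.712) and Fak (log2 0.09) were not called, sn rose, and btl was below the filter.

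Matrix, eggshell and membrane traffic groups also differed between the wild-type fractions by camera at the preset correlation. Of 18 extracellular matrix genes 2 were higher, 4 lower and 12 not called, with 3 higher and 6 lower when adjusted over the list alone (median log2 -0.15; camera adjusted p = 0.0247, and 0.386 with an estimated correlation). Both collagen IV genes, vkg and Col4a1 (log2 -1.70), and the lysyl hydroxylase gene Plod (log2 -1.64) fell, whereas the prolyl hydroxylase gene PH4alphaEFB rose (log2 0.97). Of 27 eggshell, yolk and follicle genes 7 were higher, 20 were not called and 9 were higher when adjusted over the list alone (median log2 0.31; camera adjusted p = 0.00373, and 0.501 with an estimated correlation), among them Fcp3C (log2 1.57), the chorion gene Cp7Fc (log2 1.14), Vm26Ac (log2 0.96) and ndl (log2 0.79). Of 32 membrane traffic genes 5 were higher and 27 not called, with 6 higher when adjusted over the list alone (median log2 0.16; camera adjusted p = 0.00333, and 0.209 with an estimated correlation). The coat genes alphaCOP (log2 0.65), betaCOP (log2 0.61), AP-2alpha (log2 0.55) and AP-1-2beta (log2 0.46) were called. Among 22 muscle genes only Argk1 was called (log2 1.42), also when adjusted over the list alone, although the group median was 0.46 (camera adjusted p = 0.00226, and 0.166 with an estimated correlation); its other probe set gave 0.21.

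Oxidative phosphorylation genes and some chaperone and mitotic cell cycle genes were lower in wild-type migratory cells. Of 59 oxidative phosphorylation genes 20 were lower, none was higher and 39 were not called, and 32 were lower when adjusted over the list alone (median log2 -0.39; camera adjusted p = 1.20e-12, and 0.166 with an estimated correlation). ATPsynO (log2 -0.66), SdhB (log2 -0.75), ATPsynD (log2 -0.51) and ND-19 (log2 -0.71) were among them. Of 15 heat shock and chaperone genes 5 were lower, 1 higher and 9 not called, with the same counts when adjusted over the list alone (median log2 -0.30; camera adjusted p = 0.0125, and 0.217 with an estimated correlation). The mitochondrial chaperone genes Hsp60A (log2 -1.54) and CG11267 (log2 -1.18) and DnaJ-1 (log2 -0.48) fell, and Gp93 rose (log2 0.72). Of 29 mitotic cell cycle genes 3 were lower and 26 not called, again 3 when adjusted over the list alone (median log2 -0.33; camera adjusted p = 0.0125, and 0.135 with an estimated correlation), namely the replication genes dpa (log2 -1.50), Mcm2 (log2 -0.91) and PCNA (log2 -0.64). None of 29 ribosomal protein genes was called, or called when adjusted over the list alone, while their median was -0.22 (camera adjusted p = 3.19e-06, and 0.409 with an estimated correlation); RpS20 (log2 -0.35, adjusted p = 0.0583) and RpLP0 (log2 -0.32, adjusted p = 0.0625) came nearest. The GAPDH 5' to 3' ratio, a measure of RNA integrity, was 0.0854 (SD 0.00839) in the wild-type migratory arrays and 0.175 (SD 0.0217) in the nonmigratory arrays. With that ratio as a covariate, chosen after the values were seen, 4 features were called for WT migratory vs nonmigratory in place of 825. The ratios did not overlap between these fractions, so the lower count cannot show whether RNA integrity accounts for the other changes. Genes called in lists that camera did not call included dpp (at least 2.69-fold higher, adjusted p = 0.0150), the nuclear receptor genes ftz-f1 (log2 1.60) and Hr4 (log2 1.49, with 0.70 on its other probe set), PGRP-LB (log2 1.57) and the antimicrobial gene Drs (log2 -1.74). Values of the 3 arrays of each fraction did not overlap for 25.1% of features, where 10% is the share by chance. In 1976 features the unadjusted p was below the level used.

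In the slbo mutant the fractions differed in many of the same genes. yellow-k rose 8.53-fold in mutant migratory cells (log2 3.09, SE 0.173, n = 3 per group, adjusted p = 1.89e-07), and goe (log2 2.87, SE 0.210), Cda5 (at least 3.92-fold) and the zona pellucida domain gene neo (log2 2.53, SE 0.256) rose with it. The lipase gene mag (log2 2.44, SE 0.576), the serine protease genes Jon99Fii (log2 2.27, SE 0.285) and Jon99Fi (log2 2.14, SE 0.359) and the peptidoglycan recognition gene PGRP-LB (log2 2.17, SE 0.191) also rose. Rtc1 (log2 -2.39, SE 0.389), Irp-1B (log2 -2.36, SE 0.265), Shmt (log2 -2.19, SE 0.385), Drs (at least 3.29-fold), the ubiquinone synthesis gene Coq5 (at least 2.58-fold), vkg (log2 -1.84, SE 0.173), Hesr (log2 -1.82, SE 0.222) and the mitochondrial import gene Tom40 (3.48-fold lower, SE 0.310 on the log2 scale) fell. In total 801 features were called, 334 higher and 467 lower, and 169 and 132 of them changed at least 2-fold. For slbo migratory vs nonmigratory the count was 94 with the gut list mean as a covariate, 438 without mutant migratory replicate 2, 373 without mutant nonmigratory replicate 1 and 435 without mutant nonmigratory replicate 2. The unadjusted p was below the level used for 2034 features, and 29.8% had no overlap between the fractions, against 10% by chance.

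Eggshell genes were raised in mutant migratory cells, 10 of 27 higher, 17 not called and 11 higher when adjusted over the list alone (median log2 0.52; camera adjusted p = 3.40e-09, and 0.285 with an estimated correlation). Examples were tsl (at least 3.03-fold), Fcp3C (log2 1.79), the chorion gene Cp36 (log2 0.98) and psd (log2 0.86). Of 31 detoxification genes 5 were higher, 1 lower and 25 not called, with 8 higher and 2 lower when adjusted over the list alone (median log2 0.37; camera adjusted p = 0.00918, and 0.148 with an estimated correlation). GstD2 (log2 1.42), the metallothionein gene MtnA (log2 1.32) and GstD3 (log2 1.03) rose, whereas the mitochondrial superoxide dismutase gene Sod2 fell (log2 -0.81). Of 22 muscle genes 2 were higher, Zasp66 (log2 1.52) and Argk1 (log2 0.79), and 20 were not called, with 3 higher and 1 lower when adjusted over the list alone (median log2 0.37; camera adjusted p = 0.00855, and 0.285 with an estimated correlation). Gut genes rose in 4 of 30 cases with 26 not called, and in 11 when adjusted over the list alone (median log2 0.82; camera adjusted p = 6.91e-08, and 0.362 with an estimated correlation); Npc2d (at least 2.27-fold) and Jon65Ai (log2 1.30) joined Jon99Fi and Jon99Fii. The mean of the gut list was 8.91, 9.34 and 8.91 on the mutant migratory arrays and 7.79, 8.23 and 8.15 on the mutant nonmigratory arrays.

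Of the 59 oxidative phosphorylation genes 26 were lower in mutant migratory cells, 33 were not called, and 39 were lower and 1 higher when adjusted over the list alone (median log2 -0.43; camera adjusted p = 5.59e-14, and 0.271 with an estimated correlation). SdhB (log2 -0.92), ATPsynB (log2 -0.79), ATPsyngamma (log2 -0.68) and ATPsynO (log2 -0.65) were called. Of 15 heat shock and chaperone genes 5 were lower and 10 not called, 6 lower when adjusted over the list alone (median log2 -0.48; camera adjusted p = 2.78e-05, and 0.148 with an estimated correlation), with Hsp60A (log2 -1.36), Hsc70-5 (log2 -1.03), CG11267 (log2 -0.95) and DnaJ-1 (log2 -0.70) among them. Proteasome genes were lower in 2 of 29 cases with 27 not called, Prosalpha7 (log2 -0.44) and Prosalpha3 (log2 -0.40), the same 2 counted when adjusted over the list alone (median log2 -0.21; camera adjusted p = 0.000435, and 0.571 with an estimated correlation). Of 18 matrix genes 1 was higher, 3 lower and 14 not called, with 2 higher and 7 lower when adjusted over the list alone (median log2 -0.18; camera adjusted p = 0.01004, and 0.362 with an estimated correlation). vkg, Plod (log2 -1.53) and Col4a1 (log2 -1.43) fell here too, and PH4alphaEFB rose (log2 0.63). The GAPDH 5' to 3' ratio was 0.119 (SD 0.0288) in mutant migratory and 0.165 (SD 0.0272) in mutant nonmigratory arrays, and 168 features were called for slbo migratory vs nonmigratory with it as a covariate.

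Fraction differences were shared between genotypes, although the log2 changes of the comparisons used no array in common. Calls in both rested on the same variance estimate of each feature, so the counts expected from independent lists may be too low. In both genotypes 161 genes were higher in migratory cells, where 14.2 were expected from independent lists, 271 were lower, where 22.99 were expected, and 1 was called in opposite directions. Of the 383 features enriched in wild-type migratory cells 366 changed with the same sign in the mutant, as did 426 of the 442 depleted features, and the log2 changes correlated at r = 0.470 across genes. Averaged over genotypes, yellow-k (log2 3.25, adjusted p = 6.67e-10), goe (log2 2.89), Cda5 and osy (log2 2.01) were raised, and Irp-1B, Shmt (log2 -2.29), l(1)G0020 and vkg (log2 -1.95) were lowered. The average called 1610 features, 722 higher and 888 lower. The GAPDH 5' to 3' ratio was lower on average in migratory cells of both genotypes, with overlap in the mutant. For migratory vs nonmigratory averaged over genotypes the count was 36 with that ratio and 726 with the gut list mean as a covariate. The average called 12 of 27 eggshell genes (median log2 0.42; camera adjusted p = 5.34e-06, and 0.320 with an estimated correlation) higher. So were 8 of 22 muscle genes (median log2 0.39; camera adjusted p = 0.00135, and 0.132 with an estimated correlation). It called 40 of 59 oxidative phosphorylation genes lower (median log2 -0.39; camera adjusted p = 9.43e-16, and 0.131 with an estimated correlation). Across all 12 arrays the first principal component held 22.5% of the variance and separated the fractions.

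**Figure D2:**
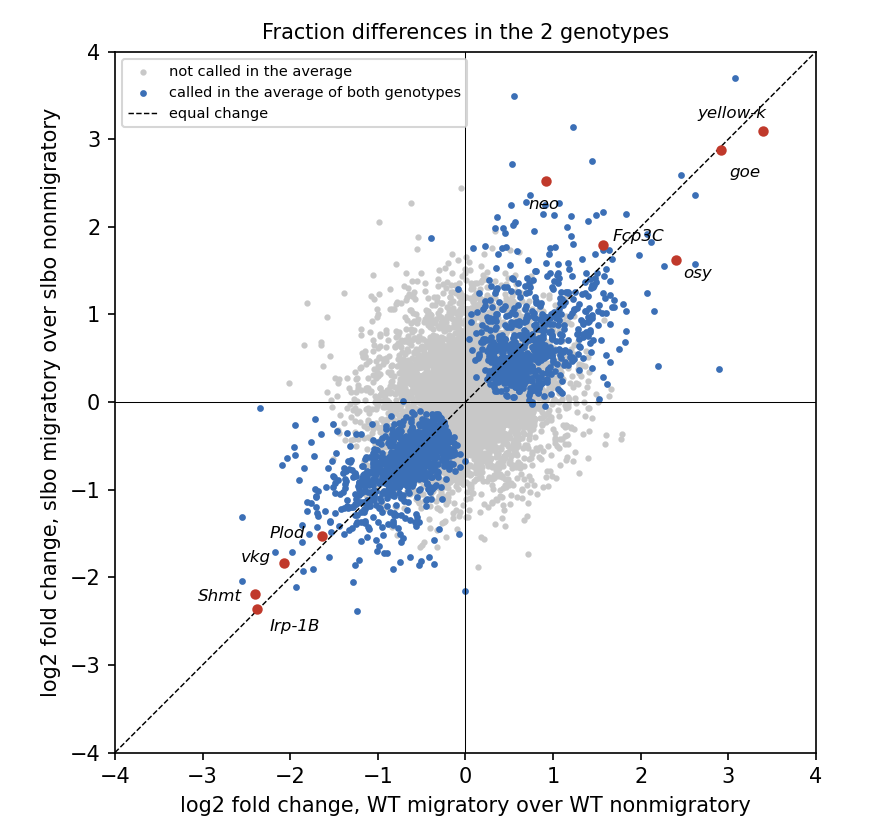
Change between migratory and nonmigratory cells in the wild type against the same change in the slbo mutant. Each point is 1 feature, blue points were called in the average over genotypes, and named genes are marked in red.

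Loss of slbo in migratory cells was accompanied by much higher levels of digestive enzyme transcripts. LysC rose at least 59.99-fold (n = 3 per group, adjusted p = 6.51e-11), from a mean signal of 24.8 to 2196. The annotation used gives its probe set to LysC alone, but the probe set may bind transcripts of related lysozyme genes. The signal of 24.8 lay under the 95th percentile of absent control probe sets, 36.7, on 2 of 3 arrays, and folds against such signals are given as bounds. LysD (log2 4.04, SE 0.438), LysB (log2 2.77, SE 0.265), the amylase gene Amy-d (log2 3.11, SE 0.517), the mannosidase genes LManVI (log2 2.94, SE 0.321) and LManV (log2 2.84, SE 0.473), the acyl-CoA binding protein gene Acbp2 (at least 5.16-fold) and the lipase gene mag (at least 4.12-fold) rose too. The other probe set of LManV gave 0.50. The nucleotidase gene NT5E-2 fell at least 6.85-fold (adjusted p = 0.000628), and slbo fell. mRpL21 (log2 -1.36, SE 0.268), the receptor tyrosine kinase gene Tie (log2 -1.36, SE 0.293), CHKov1 (log2 -1.33, SE 0.209), the Maf factor gene tj (log2 -1.31, SE 0.270), Tom40 (log2 -1.31, SE 0.310) and Dph1 (log2 -1.26, SE 0.228) fell as well. CG4962, picked out after the values were seen, fell at least 31.9-fold (adjusted p = 4.94e-07). At n = 3 per group 174 features were called, 102 higher and 72 lower, and 90 and 30 of these changed at least 2-fold. For slbo migratory vs WT migratory the count was 100 without the variance trend, 115 with only the 2 groups fitted and 39 with the GAPDH ratio as a covariate. With arrays centred on their medians the split for slbo migratory vs WT migratory was 84 higher and 126 lower, and the median change moved from 0.0105 to -0.113.

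Gut genes accounted for the clearest group difference between mutant and wild-type migratory cells. All 30 members had positive changes, 11 were called higher and 19 were not called, and 22 were higher when adjusted over the list alone (median log2 1.64; camera adjusted p = 5.53e-27, and 0.247 with an estimated correlation). LysE (log2 2.46) and the protease gene Jon25Bii (log2 2.39) were among them. The mean of the gut list was 8.91, 9.34 and 8.91 on mutant migratory arrays and 7.46, 6.65 and 7.86 on wild-type migratory arrays. With that mean as a covariate, chosen after the values were seen, 2 features were called for slbo migratory vs WT migratory in place of 174. The mean was formed from genes of this result and did not overlap between the groups, so it could not be separated from genotype. The lower count therefore cannot show that gut tissue accounts for the other changes. Germline genes had a raised median of 0.39 with 1 of 40 called, swa (log2 1.30, with -0.26 on its other probe set), 39 not called, and 2 higher when adjusted over the list alone (camera adjusted p = 0.000883, and 0.342 with an estimated correlation). The detoxification genes Cyp6a13 (at least 5.01-fold) and Cyp9b2 (log2 2.32, with 0.39 on its other probe set) rose in a list that camera did not call (adjusted p = 0.0925) and fry did (adjusted p = 0.00839). The matrix peroxidase gene Pxn rose too (log2 1.47, adjusted p = 0.0427).

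**Figure D3:**
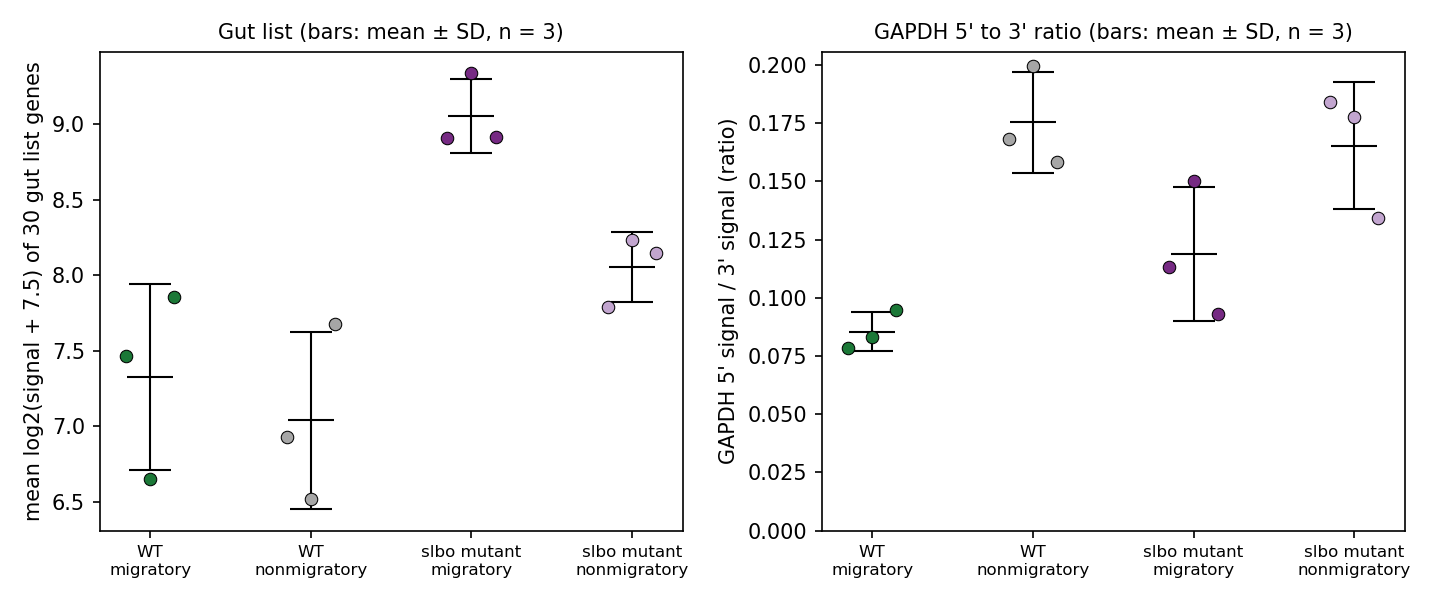
Mean of the gut gene list and GAPDH 5' to 3' ratio on each of the 12 arrays. Both are shown by genotype and cell fraction.

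By camera at the preset correlation, adhesion, eggshell, actin, membrane traffic and proteasome genes were lower in mutant migratory cells, with few members called. Of 42 adhesion and polarity genes 1 was lower, the neurotactin gene Nrt (log2 -0.97, adjusted p = 0.0145, with -0.44 on its other probe set), 41 were not called, and 5 were lower when adjusted over the list alone (median log2 -0.30; camera adjusted p = 0.000204, and 0.247 with an estimated correlation). Of 27 eggshell genes 2 were lower, Fcp3C (log2 -0.72) and ndl (log2 -0.71), 25 were not called, and 1 was higher and 9 lower when adjusted over the list alone (median log2 -0.36; camera adjusted p = 3.57e-05, and 0.395 with an estimated correlation). Of 44 actin genes only the capping protein gene cpb was called (log2 -1.15, adjusted p = 0.00433), also when adjusted over the list alone (median log2 -0.15; camera adjusted p = 0.0209, and 0.262 with an estimated correlation). No membrane traffic gene of 32 was called and 1 was lower when adjusted over the list alone, with alphaCOP (log2 -0.44, adjusted p = 0.0636) and AP-2alpha (log2 -0.41, adjusted p = 0.180) as examples (median log2 -0.13; camera adjusted p = 0.00772, and 0.269 with an estimated correlation). Of 29 proteasome genes Rpt5 was lower (log2 -0.89, adjusted p = 0.000508) and 28 were not called, again 1 when adjusted over the list alone (median log2 -0.14; camera adjusted p = 0.000667, and 0.518 with an estimated correlation). PH4alphaEFB (log2 -0.80), the tubulin gene alphaTub84D (log2 -0.65) and Gp93 (log2 -0.59) fell and E(spl)m3-HLH rose (log2 1.09). Among the genes expected to depend on slbo, sn (log2 -0.73, adjusted p = 0.128), jing (log2 -0.82, adjusted p = 0.359, with 0.77 on its other probe set), shg (log2 -0.14, adjusted p = 0.863) and Fak (log2 0.13) were not called. Values did not overlap for 18.3% of features, against 10% by chance, and the unadjusted p was below the level used for 1175. For slbo migratory vs WT migratory without mutant migratory replicate 1 the count was 79, and without mutant migratory replicate 3 it was 96. The other probe set of Nrt gave 0.15 between wild-type fractions and -1.24 between genotypes in nonmigratory cells.

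Of the 383 features enriched in wild-type migratory cells, 36 were lower and 8 higher in mutant migratory cells, where independent lists would give 3.07 and 4.35. Genes picked out after the values were seen included, among the lower ones, Tie, CHKov1, Nrt, Fcp3C, ndl, PH4alphaEFB, GstD4, Gp93, Tsf2, wun and Inx2, and among the higher ones neo, Jon99Fii and Jon65Aii. Both comparisons share the wild-type migratory arrays and the variance estimate of each feature. In 20 simulated mutants without change the highest counts lower and higher were both 0. No feature was changed there, so hardly any call could arise, and these counts cannot show how far shared arrays raise the 36. The share with a negative sign was 85.6%, against 62.9% in those simulations. Of the 442 depleted features 2 were lower and 9 higher in the mutant, against 3.54 and 5.02 for independent lists. The enriched features had a median change of -0.32 in mutant migratory cells, against -0.06 for the mean of the medians in those simulations. Noise was drawn there independently for each feature, whereas related genes moved together on the real arrays, and observed wild-type means were taken as true. Neither 62.9% nor -0.06 therefore measures the full effect of shared arrays. Over all features the covariance of the 2 comparisons was -0.0760, against a mean of -0.0743 in the simulations without change. For migratory-enriched genes in the slbo mutant the 36 became 21 without wild-type migratory replicate 1, 21 without wild-type migratory replicate 3, 12 without mutant migratory replicate 1 and 16 without mutant migratory replicate 3, and 0 and 1 with the GAPDH ratio and the gut list mean as covariates.

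Mutant nonmigratory cells also had higher lysozyme and amylase transcripts, and lower levels of several chorion genes. LysC rose at least 34.0-fold (n = 3 per group, adjusted p = 3.07e-10), with LysD (log2 4.36, SE 0.438), Amy-d (log2 2.63, SE 0.517) and the protease gene Jon25Biii (log2 2.24, SE 0.385). NT5E-2 (at least 3.97-fold), GstE14 (at least 3.16-fold), Mur2B (log2 -1.65, SE 0.321) and the chorion gene Cp19 (log2 -1.36, SE 0.203, adjusted p = 0.00643) fell. Of 27 eggshell genes 7 were lower, 20 were not called, and 20 were lower and 1 higher when adjusted over the list alone (median log2 -0.44; camera adjusted p = 6.05e-19, and 0.272 with an estimated correlation), with Fcp3C (log2 -0.93), Cp15 (log2 -0.91) and dec (log2 -0.67) beside Cp19. Of 30 gut genes 5 were higher and 25 not called, and 11 were higher when adjusted over the list alone (median log2 0.84; camera adjusted p = 1.03e-13, and 0.519 with an estimated correlation), including LysE (log2 2.15), LysB (log2 2.03) and Jon25Bii (log2 1.74). The gut list mean was 7.79, 8.23 and 8.15 on these arrays and 6.93, 6.52 and 7.68 on wild-type nonmigratory arrays. No germline gene of 40 was called and 2 were higher when adjusted over the list alone (median log2 0.35; camera adjusted p = 4.69e-05, and 0.519 with an estimated correlation), with osk (log2 1.38, adjusted p = 0.107) and gcl (log2 0.78, adjusted p = 0.143) nearest. No ribosomal protein gene of 29 was called and 6 were lower when adjusted over the list alone (median log2 -0.22; camera adjusted p = 8.58e-10, and 0.546 with an estimated correlation), with RpLP2 (log2 -0.32, adjusted p = 0.224) and RpS28a (adjusted p = 0.175) as examples. The single genes cpb (log2 -0.92), Rpt5 (log2 -0.59), ATPsynF (log2 -0.54), alphaTub84D (log2 -0.86), GstS1 (log2 -0.87), Pxn (at least 2.80-fold) and Cyp6a13 (at least 2.89-fold) changed too. In all 60 features were called, 28 higher and 32 lower, and 19 and 17 of these changed at least 2-fold. For slbo nonmigratory vs WT nonmigratory the count was 16 without the variance trend. It was 30 and 29 without wild-type replicates 1 and 2, 25, 16 and 26 without mutant replicates 1, 2 and 3, and 22 with the gut list mean as a covariate. With a replicate block it was 32. The unadjusted p was below the level used for 826, and 15.4% did not overlap, against 10% by chance.

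**Figure D4:**
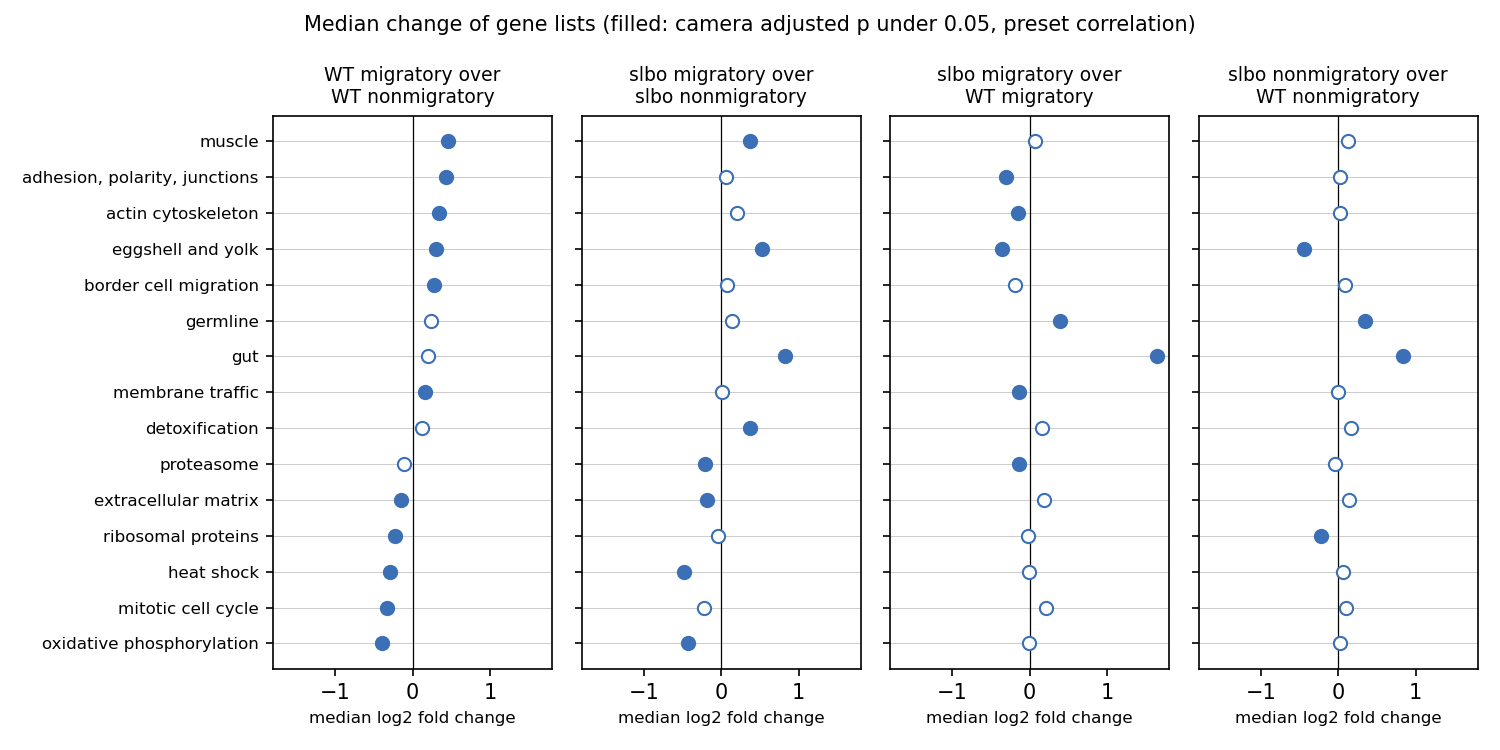
Median log2 change of gene lists between fractions within each genotype and between genotypes within each fraction. Only lists that passed the camera test at the preset correlation in any of these comparisons are shown. Other tested lists, the interaction and the average over genotypes are left out. Filled marks passed the camera test at the preset correlation.

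No single gene was called for a fraction difference that depended on genotype. By limma 0 features were called for the interaction of genotype and fraction at n = 3 per group, with 603 below the level used before adjustment, and 0 were called in each other limma setting run on all 12 arrays; without wild-type migratory replicate 3, 2 were called. The genes with the lowest unadjusted p that met the rule for named genes had positive values for Acbp6 (log2 1.72, adjusted p = 0.213), mesh (log2 1.38, adjusted p = 0.360), neo (log2 1.61, adjusted p = 0.423), Cyp6d5 (log2 1.76, adjusted p = 0.427) and Acbp2 (log2 1.91, adjusted p = 0.457). They had negative values for teq (log2 -1.11, adjusted p = 0.260), cindr (log2 -0.95), Gp93 (log2 -0.70), ndl (log2 -0.64) and flw, the last 4 each with an adjusted p of 0.423. The other probe sets gave 0.03 for mesh and -0.30 for cindr. They pointed the other way for flw (1.14) and for 2 of 3 in teq (0.68, 0.80 and -0.30). For slbo itself it was -0.98 (SE 0.572, adjusted p = 0.787). As groups, gut genes had a positive interaction (median log2 0.73; camera adjusted p = 2.45e-05, and 0.537 with an estimated correlation), as did eggshell genes (median log2 0.32; 0.000547 and 0.537 with an estimated correlation) and ribosomal protein genes (median log2 0.16; 4.43e-05 and 0.544 with an estimated correlation). For eggshell genes the mutant value was negative in both fractions and lower in nonmigratory cells, with medians of -0.36 and -0.44. For ribosomal protein genes the medians were -0.02 and -0.22. Adhesion and polarity genes had a negative interaction (median log2 -0.25; camera adjusted p = 0.000151, and 0.449 with an estimated correlation), as did border cell migration genes (median log2 -0.16; 0.0378 and 0.449 with an estimated correlation), membrane traffic genes (median log2 -0.12; 0.0422 and 0.537 with an estimated correlation) and proteasome genes (median log2 -0.14; 0.0378 and 0.703 with an estimated correlation). No gene of these groups was called for the interaction.

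Lists that camera called in no comparison included several with a role in ovarian signalling. Their medians between wild-type fractions were 0.27 for follicle cell patterning, 0.21 for JAK-STAT, 0.19 for ecdysone, 0.18 for receptor tyrosine kinase and Ras, 0.16 for small GTPase, -0.0003 for Notch and -0.17 for JNK and dissociation stress genes. They were 0.12 for innate immunity, 0.23 for trachea, 0.28 for neuron and glia and 0.14 for tubulin and motor genes. Median and mean differed in sign for hemocyte genes (0.18 and -0.14), fat body genes (0.002 and -0.03) and homeodomain genes (-0.10 and 0.02), where camera took the sign of the mean. By fry, follicle cell patterning and small GTPase genes (adjusted p = 0.0372 each) and tubulin and motor genes (0.0234) passed between wild-type fractions, and innate immunity (0.0270) and hemocyte genes (0.00795) passed in the average. Of 37 list results that passed over the first 5 comparisons, 0 passed with an estimated correlation, and the rotation test fry called 24, of which 17 were shared. Centring the arrays turned the sign of the median in 0 of 51 list results counted over 6 comparisons.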

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

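All tests of explanations in these paragraphs were chosen after the result they address was seen, whereas the splits of arrays were planned, and the held-out tests of noise and purity replaced simulations that had excluded both.

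Gut genes and LysC were higher in the mutant in both fractions. The gut genes moved together over arrays, with a mean pairwise correlation of 0.426 within groups, against a highest value of 0.100 in 1000 random lists. Some other lists of related genes also exceeded 0.100. Their estimated correlations were 0.574 for ribosomal protein and 0.324 for eggshell genes, while actin cytoskeleton genes gave 0.022. The test therefore cannot decide whether amounts of gut tissue differed between the preparations. The fitted rise of LysC exceeded the median rise of 27 gut genes other than lysozymes by 4.43 (SD 0.734 over those genes), and its rises in the fractions differed by 0.615 (SE 0.275). LysC was the gene that rose most and its level in gut tissue was not measured, so a single amount of gut tissue remained open, and its wild-type signals lay near those of absent control probe sets, so the difference between fractions left a strain background acting alike in both open. Counting gut transcripts in dissected ovaries free of gut would separate these readings.

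Oxidative phosphorylation genes were lower in migratory cells of both genotypes. The GAPDH 5' to 3' ratio was 0.102 (SD 0.0264) on 6 migratory and 0.170 (SD 0.0227) on 6 nonmigratory arrays (exact permutation p = 0.00433, Benjamini-Hochberg 0.0130 over 3 ratios). With the GAPDH ratio as a covariate their mean change was -0.259 (SE 0.102), against -0.337 (SE 0.0461) without it, and with the eIF-4a and actin ratios, which were not called different between fractions (adjusted p = 0.0909 and 0.333, exact permutation tests), it was -0.354 (SE 0.0617) and -0.346 (SE 0.0514); the GAPDH ratio nearly separated the fractions, so RNA integrity was not excluded. A lower germline share was not seen, as the germline median was 0.224 (SE 0.0981). Lists written after related genes were seen, and without those genes, gave medians of -0.85 for ribosome assembly genes (21 of 31 lower, camera adjusted p = 1.22e-17, and 0.00377 with an estimated correlation) and -0.54 for mitochondrial ribosome genes (45 of 63 lower, 1.79e-23 and 0.00819). These p were adjusted over the 3 added lists only, unlike those of the 29 planned lists.

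Genes enriched in wild-type migratory cells were lower in mutant migratory cells. When 1 wild-type array was held out of the selection, the enriched genes had a median change of -0.255 against that array (SD 0.0674 over 3 arrays). Against replicates 1, 2 and 3 it was -0.286, -0.177 and -0.301, and for depleted genes 0.177, -0.183 and 0.0280. The fall was thus seen without noise shared through the selection. All 3 values used the same mutant arrays, so the SD leaves out their noise and cannot show how certain the fall is. Lower purity of the mutant fraction was taken to predict a rise of depleted genes at least as large as the fall of enriched ones. The rise minus the fall was -0.247 (SD 0.128 over 3 held-out arrays), and -0.237 (SD 0.113) when centred on the median change of all features. The distance from 0 relative to the SD depended on centring, and 3 arrays were too few to decide. For the 36 genes, chosen as lower in mutant migratory cells, a genotype difference in both fractions remained possible. Their median change was -0.355 in nonmigratory cells (SE 0.0672 for their mean), against -0.844 in migratory cells. Over all 383 enriched features the median was 0.0231 in nonmigratory cells, against -0.32 in migratory cells, so the set as a whole did not fall in nonmigratory cells. Secretory pathway genes, a list written after related genes were seen and without those genes, had a median of -0.23 with 0 of 32 called (camera adjusted p = 2.23e-08, and 0.0622 with an estimated correlation). Both p were adjusted over the 3 added lists only.

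For lists that camera called for the interaction, mean changes were -0.218 for border cell migration, -0.286 for adhesion and polarity, 0.254 for eggshell, 0.714 for gut, -0.179 for membrane traffic, 0.206 for ribosomal protein and -0.0703 for proteasome genes. With an estimated correlation none passed (adjusted p from 0.449 to 0.703). The actin control probe sets were higher in migratory cells, by a ratio of 1.46 for the 3' set (4714, SD 391, against 3226, SD 396; exact permutation p = 0.00216, the smallest possible) and of 1.48 for the middle set (6323 against 4282, exact permutation p = 0.00216). Other control probe sets were lower in migratory cells, with ratios of 0.619, 0.790 and 0.808 for the 5', middle and 3' sets of eIF-4a and of 0.603 for the 5' set of GAPDH. When arrays were split against the labels, 10 splits of 3 against 3 were too few for a share under 0.05. The real and highest other counts were 825 and 6 between wild-type fractions, 801 and 0 between mutant fractions, 174 and 1 between genotypes in migratory cells and 60 and 0 in nonmigratory cells. The real count was the highest in 1 of 100 splits for the average, 1610 against 254. For the interaction it was 0, reached by 100 of 100 splits, of which the highest gave 417. No count can lie below 0, so this share was fixed in advance. The splits also mixed fractions and genotypes, so they say nothing about the interaction.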

How the results depend on the processing

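The cause of each change listed here was not tested. For the targeted gene slbo the alternatives lay between -2.25 and -1.71, and the call was lost with the GAPDH ratio (-1.91) or the gut list mean (-2.04) and without wild-type migratory replicate 1 (-1.90) or mutant migratory replicate 1 (-2.11) or 3 (-1.97). For WT migratory vs nonmigratory the count was 503 without the variance trend, 495 with 2 groups and 4 with the GAPDH ratio, and 518, 537 and 451 without wild-type migratory replicate 1 or 3 or wild-type nonmigratory replicate 2 (range 451 to 962). For slbo migratory vs nonmigratory it was 436 without trend, 168 with the GAPDH ratio and 94 with the gut list mean, and 438, 373 and 435 without mutant migratory replicate 2 or mutant nonmigratory replicate 1 or 2 (range 373 to 967). For slbo migratory vs WT migratory it was 100 without trend, 115 with 2 groups, 39 with the GAPDH ratio and 2 with the gut list, and 79 and 96 without mutant migratory replicate 1 or 3 (range 79 to 190). For slbo nonmigratory vs WT nonmigratory it was 16 without trend and 22 with the gut list, 30 and 29 without wild-type replicate 1 or 2, and 25, 16 and 26 without mutant replicate 1, 2 or 3 (range 16 to 70). The interaction of genotype and cell fraction had 2 calls without wild-type migratory replicate 3. For migratory vs nonmigratory averaged over genotypes it was 36 with the GAPDH ratio and 726 with the gut list (range 1285 to 1784 without single arrays). In rib, migratory vs nonmigratory averaged over genotypes, 1.31 became -0.15 with the GAPDH ratio (adjusted p = 0.963). For migratory-enriched genes in the slbo mutant the lower ones numbered 0 with the GAPDH ratio, 1 with the gut list, 21 and 21 without wild-type migratory replicate 1 or 3, 12 and 16 without mutant migratory replicate 1 or 3, and 12 to 38 over all arrays. In the gene list tests 0 of 37 results passed with an estimated correlation and 17 of 37 with fry, which called 24 in total. Without single arrays the total called by camera was 34 to 43. Residual correlations of replicates with the same number ran from -0.0760 to 0.0830; between wild-type fractions 3 of 3 arrays matched their own number best, and between the other pairs of groups 0, 0 and 2 did. A replicate block gave 858, 855, 130 and 32 calls in the 4 comparisons of 2 groups, 0 for the interaction and 41 lists. Of 296 results for named genes, those that became weaker numbered 211 with the GAPDH ratio, 130 with the gut list, 76 without trend, 33 of the 195 run with 2 groups, 28 with the block, 24 with centring, 17 with probe set means, 16 without filter, 7 with quantile normalization, 6 with weights, 6 with a constant of 1% and 2 of the 290 run with the higher filter. Leaving out single arrays weakened 431 of 3552 gene results and 29 of 444 list results.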

Other observations

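The ecdysone list as a whole was not called in the average over genotypes, with 4 of 18 members higher, 3 lower, 11 not called and a median of -0.03 (camera adjusted p = 0.697). Among its members the nuclear receptor genes Hr4 rose by 1.43 (adjusted p = 1.98e-05, with 0.29 on its other probe set) and ftz-f1 rose by 1.39 (adjusted p = 5.27e-05) on the log2 scale, and ImpL2 by 0.74 (adjusted p = 3.04e-05), while Cth fell by 0.79 on the log2 scale (adjusted p = 0.000411). The Notch targets E(spl)m3-HLH (log2 -0.78) and E(spl)malpha-BFM (log2 -1.24) were lower and fng was higher (log2 0.40). Collagen IV genes and Plod fell in both genotypes, with Plod at -1.58 (adjusted p = 2.17e-07) and Col4a1 at -1.56 (adjusted p = 7.44e-07).

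A first hypothesis is that migratory cells make less collagen IV than the remaining ovary cells, which staining of both fractions would test together with hemocyte markers, since vkg and Col4a1 are also on the hemocyte list. Secretory pathway genes were higher in migratory cells in the average, 15 of 32 higher and none lower (median log2 0.25; camera adjusted p = 1.87e-06, and 0.0453 with an estimated correlation), where ribosome assembly genes were lower. The secretory list was written after related genes were seen and without those genes. Its p were adjusted over the 3 added lists only, and in the average both camera values equalled the unadjusted ones. In the wild type 10 of 32 were higher (camera adjusted p = 1.64e-09, and 0.0171 with an estimated correlation). In the mutant 1 was higher (camera adjusted p = 0.0119, and 0.247 with an estimated correlation, fry adjusted p = 0.0402). The difference between genotypes had a camera adjusted p of 4.31e-05 for the interaction, and 0.190 with an estimated correlation, with 0 of 32 called. Another hypothesis is that slbo raises Tie in migratory cells, which a rescue of slbo would test. A further hypothesis is that the lysozyme increase belongs to the strain and not to slbo; a different slbo allele in another background would test it.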
